A study of Homo sapiens with 20 samples.

How the data were processed

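The samples were HEK 293T cells, a transformed human embryonic kidney line, treated for 1 h with DMSO, the solvent, or with 5 µM i14G1-12. The title of the series sets this in the context of an inhibitor of eIF1-eIF4G1, both initiation factors and named as a pair. Per the labels' protocols, cells were crosslinked with formaldehyde, the lysate was digested with RNase I, and complexes were separated by ultracentrifugation. Small ribosomal subunit complexes were then immunoprecipitated through HA (HA-tagged eIF1), eIF4G1, HA-tagged eIF2a or eIF3, and the RNA recovered from them was sequenced. This is selective translation complex profiling, which reads the footprints of initiation complexes that hold a chosen factor. There were 20 libraries in 8 groups, with 3 libraries per group for eIF1 and eIF4G1 and 2 per group for eIF2a and eIF3. No input library was analysed here, so a value is a share of the RNA in an immunoprecipitate and not an occupancy per mRNA.

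The authors deposited raw read counts per gene in 4 tables, 1 for each immunoprecipitation, in the column layout that featureCounts writes. Per the submitters' processing notes, the tools were cutadapt, Trimmomatic, Bowtie, HISAT2 and featureCounts, and the genome build was hg38, with no versions given. Per the file headers, the 4 tables share 19029 Ensembl gene IDs, and each ID has a sequence that starts at 1 on a contig named by the gene, so reads were counted on 1 transcript sequence per gene. Of these rows, 19025 list a single interval and 4 repeat it. How reads that fit several genes were handled is not given in the sources used here. Reads of near-identical genes can therefore be split or lost. A search for pairs of IDs whose counts differed by 15% or less in every library where the pair had at least 200 counts found 10 pairs (20 IDs) at a minimum total of 2000 counts. At a minimum total of 20000, which was added after those pairs were seen, 3 pairs were left. These 20 IDs held 1.53% to 4.59% of a library's counts. Near-equal counts do not show a shared sequence, and genes that share reads can have unequal counts. The search therefore does not bound the reads that fit several genes.

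The files do not pair the IDs with gene names, and 0 of the 19029 IDs could be matched to a symbol in the reference table, whose Ensembl column was empty. Genes are therefore given by ID only. The 17 gene lists fixed before the data were examined, the shares of RNA classes, the comparison with 5′ UTR length and the runs without mitochondrial, histone or noncoding RNA genes need names or annotation and were not run. The length of the whole counted sequence was used in place of the 5′ UTR length, but it does not measure it. Results on sequence length therefore do not bear on the 5′ UTR. Of the sequence lengths, 34.5% are multiples of 3, so they are not coding lengths.

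Columns were assigned to samples by their names. The eIF1 columns carry numbers that are not the replicate numbers of the labels, so they were assigned to their group only and are called a, b and c here, with no pairing. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Replicates of a group differed by more than counting noise in every pair (chi-square over degrees of freedom 1.34 to 10.2), so none was counted as a duplicate.

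Each treatment comparison was fitted on its own libraries with edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit, glmQLFTest) after filterByExpr (minimum count 10) and TMM scaling, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Differences between treatment effects and between the DMSO groups were tested as contrasts of 1 fit to all 20 libraries. All adjusted p-values of single genes are from edgeR's quasi-likelihood test, and an SE is the absolute log2 fold change over the square root of F. CPM values are those of edgeR's cpm function on TMM-scaled libraries. Lists of genes called in one immunoprecipitation were tested in the others, 9 tests in all, with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry. That choice of lists was made after the data were seen. The rule for named genes was an adjusted p past the threshold, no overlap between the libraries of the groups compared, a mean CPM of at least 10 in the higher group, and then the largest rises and falls. Because IDs have no names here, at most 2 in each direction are given per comparison. Where no gene passed in a direction, the one with the smallest p is given.

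Alternatives were DESeq2 size factors, total counts only, no filter on low counts, a minimum of 30 counts, the DESeq2 1.42.0 test, all 20 libraries in 1 fit, the replicate number as a block, a minimum CPM of 20, a prior count of 5 and leaving out each library. Libraries that share a replicate number were not treated as paired.

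Total counts ran from 10033 to 1161512 per library. A count of 0 allows up to 2.58 CPM in the deepest library and up to 299 CPM in the shallowest (3 counts of the total), and such floors cover counting error only. Each test was tested on simulated counts with the real means, library sizes and spread and 200 changed genes. For edgeR the filter was applied again to these counts, and its shares are of the changed genes that passed. In edgeR, 4-fold changes were recovered for 83.2% of genes in the eIF1 comparison (8071 genes tested), 88.6% in eIF4G1 (6720 genes), 82.7% in eIF2a (4076 genes) and 0% in eIF3 (5694 genes). For 2-fold changes the shares were 30.6%, 13.7%, 12.0% and 0%. Unchanged genes called numbered 6, 9, 3 and 0. For the difference between the eIF1 and eIF4G1 effects, 33.0% of 4-fold and 5.15% of 2-fold changes were recovered among 8991 genes.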

Results

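Initiation complexes holding eIF1, eIF4G1, eIF2a or eIF3 were immunoprecipitated from HEK 293T cells treated for 1 h with DMSO or with 5 µM i14G1-12, and the mRNA footprints in them were counted per gene. Each immunoprecipitation had its own DMSO libraries, 3 against 3 for eIF1 and eIF4G1 and 2 against 2 for eIF2a and eIF3. Total counts were 971315 ± 178890 (SD, n = 3) for eIF1 in DMSO and 556071 ± 48915 (SD, n = 3) in i14G1-12. For eIF4G1 they ranged from 243145 to 1085854 over the 6 libraries. The 2 eIF2a DMSO libraries held 269816 and 10033 counts, and the 2 eIF3 DMSO libraries 582437 and 59179. Only 118 genes had 10 or more counts in the shallowest of these.

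**Figure D1:**
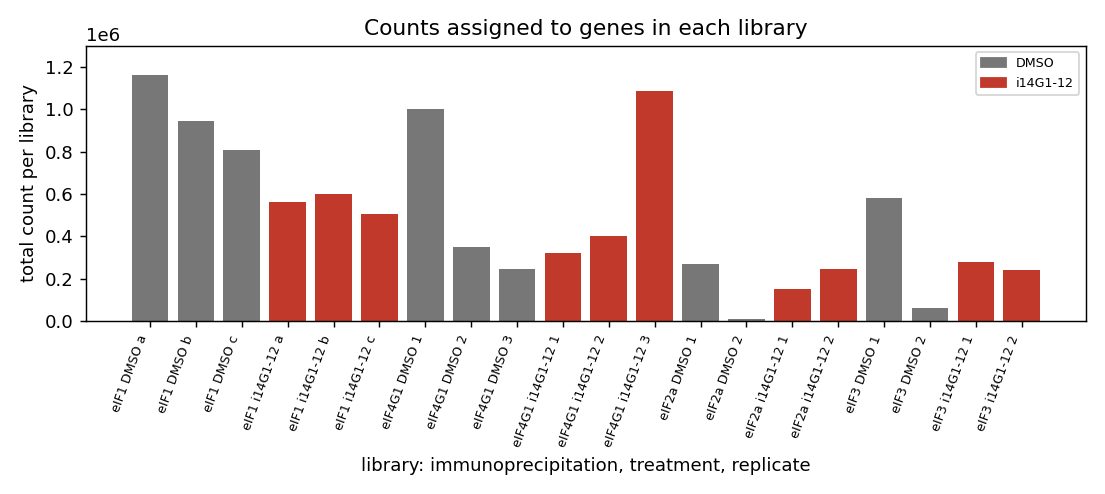
Total count assigned to genes (y axis) in each of the 20 libraries (x axis), 1 bar per library, grey for DMSO and red for i14G1-12. The bars run from 10033 counts in eIF2a DMSO 2 to 1161512 in eIF1 DMSO a.

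The first question was which mRNAs changed in eIF1 complexes after i14G1-12. Of 8338 genes tested, 27 rose and 11 fell. ENSG00000120738 rose from 8.20 ± 3.13 to 86.1 ± 39.4 CPM (SD, n = 3 each), a log2 fold change of 3.32 (SE 0.43, edgeR adjusted p = 0.000328). ENSG00000170345 rose from 4.43 ± 4.21 to 48.0 ± 29.99 CPM (SD, n = 3 each), with a log2 fold change of 3.31 (SE 0.61, edgeR adjusted p = 0.0135). ENSG00000197111 fell from 493 ± 160 to 150.0 ± 57.0 CPM (SD, n = 3 each), a log2 fold change of -1.71 (SE 0.27, edgeR adjusted p = 0.00373). ENSG00000008988 fell from 791 ± 14.8 to 324 ± 56.7 CPM (SD, n = 3 each), a log2 fold change of -1.28 (SE 0.21, edgeR adjusted p = 0.00539). At an unadjusted p under 0.05 there were 1033 genes, where 417 were expected, and DESeq2 called 100 rises and 47 falls. Of edgeR's alternatives, no filter gave 129 genes, a minimum of 30 counts 66 and 1 fit to all 20 libraries 3 rises and 1 fall. The number of changed genes was 5 without DMSO b, 2 without DMSO c, 20 without i14G1-12 b, 4 without i14G1-12 c and 64 without DMSO a, and scaling to total counts, which moved the median log2 fold change of all genes to -0.13, gave 24 rises and 16 falls. ENSG00000170345 lost the threshold without DMSO b, DMSO c or i14G1-12 a (edgeR adjusted p up to 0.154), and ENSG00000008988 without DMSO c or i14G1-12 c (up to 0.0973) and in 1 fit to all 20 libraries (0.338).

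In eIF4G1 complexes 25 of 7203 genes rose and 0 fell. ENSG00000120738 rose from 7.69 ± 4.87 to 250 ± 148 CPM (SD, n = 3 each), a log2 fold change of 4.66 (SE 0.51, edgeR adjusted p = 8.37e-06). ENSG00000170345 had a log2 fold change of 4.70 (SE 0.81, edgeR adjusted p = 0.00549), from 2.90 ± 2.82 to 92.4 ± 90.7 CPM (SD, n = 3 each), and 1 of its DMSO libraries held 0 counts. The smallest p among genes with lower values was that of ENSG00000085231, at 134 ± 33.4 CPM in DMSO and 47.2 ± 4.82 in i14G1-12 (SD, n = 3 each), which did not pass (edgeR adjusted p = 0.105). At an unadjusted p under 0.05 there were 623 genes in both directions, where 360 were expected, and DESeq2 called 72 rises and 3 falls. In edgeR, no filter gave 63 rises and 5 falls and a minimum of 30 counts 43 rises and 3 falls. The 10 most abundant genes held 5.13% ± 0.50 of counts in DMSO and 7.26% ± 0.24 in i14G1-12 (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows; adjusted p = 0.8 over 12 tests). The count of changed genes was 5, 12 and 4 without DMSO 1, 2 and 3, 41 without i14G1-12 1 and 46 without i14G1-12 3. ENSG00000170345 lost the threshold without DMSO 1, DMSO 3 or i14G1-12 1 (edgeR adjusted p up to 0.121).

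In eIF2a complexes 0 of 4719 genes changed by edgeR, with 87 genes at an unadjusted p under 0.05 where 236 were expected, and DESeq2 called 0. In simulated counts edgeR recovered 82.7% of the 81 genes with a 4-fold change that passed its filter. DESeq2, without that filter, recovered 15% of 100, so the shares are over unlike sets. The gene with the smallest p was ENSG00000162772, at 14.2 ± 20.1 CPM in DMSO and 191 ± 158 in i14G1-12 (SD, n = 2 each; edgeR adjusted p = 0.221). Its DMSO 2 library held 0 counts, which allow up to 299 CPM there, and DMSO 1 was at 28.4 CPM. Among genes with lower values the smallest p was that of ENSG00000133275, at 165 ± 12.2 CPM in DMSO and 55.2 ± 18.7 in i14G1-12 (SD, n = 2 each; edgeR adjusted p = 1.000). ENSG00000120738 was filtered out and not tested, with 0 counts in both DMSO libraries, which allow up to 11.1 and 299 CPM, and 7 and 6 counts in i14G1-12 (42.1 and 23.7 CPM). Leaving out DMSO 1, which leaves the library of 10033 counts as the only control, gave 13 genes, leaving out DMSO 2 gave 2 and leaving out i14G1-12 2 gave 1.

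In eIF3 complexes 1 of 6300 genes changed. ENSG00000120738 rose from 10.7 ± 9.69 to 438 ± 232 CPM (SD, n = 2 each), a log2 fold change of 6.13 (SE 0.97, edgeR adjusted p = 0.0397). Among genes with lower values the smallest p was that of ENSG00000163964, at 102 ± 29.9 CPM in DMSO and 18.2 ± 13.6 in i14G1-12 (SD, n = 2 each; edgeR adjusted p = 1.000). At an unadjusted p under 0.05 there were 110 genes, where 315 were expected, and DESeq2 called 3 rises. In edgeR, no filter or a minimum of 30 counts gave 2 rises and 1 fit to all 20 libraries 5. A larger count with the replicate number as a block is given with the alternatives below. Deviations from group means correlated at 0.520 for the same number in eIF3. This was over only 2 numbers, so pairing was neither shown nor excluded. ENSG00000120738 lost the threshold without DMSO 1 (edgeR adjusted p = 0.999) and with scaling to total counts (0.0557), and 3 genes were called without i14G1-12 2. The pair of libraries numbered 2 stood apart, with a Spearman rho across genes of 0.737 with each other and 0.392 to 0.667 with the 18 remaining libraries. In simulated counts with this spread edgeR recovered 0% of 4-fold changes.

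**Figure D2:**
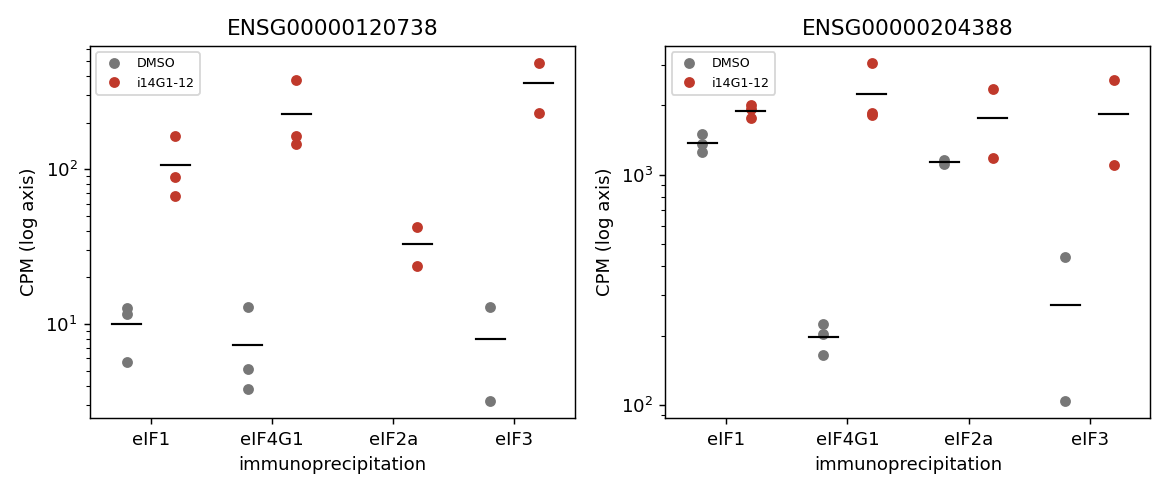
CPM (y axis, log scale) of 2 genes in each immunoprecipitation (x axis), with 1 point per library scaled over all 20, grey for DMSO and red for i14G1-12, and a black line at each group mean; both eIF2a DMSO libraries held 0 counts of ENSG00000120738 and are not drawn. In eIF1, eIF4G1 and eIF3 the i14G1-12 libraries were above the DMSO libraries for ENSG00000120738, which was not tested in eIF2a, where a count of 0 allows up to 11.1 and 299 CPM, and ENSG00000204388 was already high in DMSO in eIF1 and eIF2a.

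The genes called in eIF1 or eIF4G1 were looked up in the other immunoprecipitations. Of the risers tested in both, 7 were called in eIF1 and eIF4G1, where independent lists would share 0.0931 (26 and 25 of 6979 genes; one-sided Fisher's exact test, p = 1.90e-12, treating genes as independent). The 25 eIF4G1 risers had a median log2 fold change of 0.89 in eIF1 (25 of 25 higher), 1.41 in eIF3 (25 of 25 higher) and 0.20 in eIF2a (17 of 21 tested higher). The eIF1 risers had medians of 1.14 in eIF4G1 (26 of 26 higher), 1.22 in eIF3 (26 of 26 higher) and 0.30 in eIF2a (16 of 20 higher). The eIF1 fallers had medians of -0.59 in eIF4G1 and -0.44 in eIF3, with 10 of 11 lower in each, and of -0.02 in eIF2a, with 6 of 11 lower. Of all genes tested, 50.6% were higher in eIF1, 49.6% in eIF4G1, 56.6% in eIF2a and 51.5% in eIF3. By camera with the preset correlation, 8 of the 9 list tests passed, with adjusted p = 3.88e-27 for the eIF4G1 risers in eIF1 and adjusted p = 2.67e-40 for the eIF1 risers in eIF4G1. No list passed with an estimated correlation, where these were adjusted p = 0.102 and adjusted p = 0.0782, and by fry only the eIF1 risers in eIF4G1 passed (adjusted p = 0.0434). These lists were chosen after the data were seen. Across 4414 genes tested in all comparisons, Pearson's r between effects was 0.45 for eIF1 and eIF4G1 (Spearman's rho 0.42), 0.38 for eIF1 and eIF3 (0.37) and 0.37 for eIF4G1 and eIF3 (0.32). For eIF2a with the others r lay between 0.0752 and 0.0879. Without eIF3 DMSO 1 or eIF3 i14G1-12 1, r fell to 0.20 and 0.23 for eIF1 and eIF3, and to 0.21 and 0.17 for eIF4G1 and eIF3. Without eIF2a DMSO 1 or eIF2a i14G1-12 1, r of eIF2a with the others lay between -0.0399 and 0.0214. These are across genes, which are not independent replicates, so no p is given.

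**Figure D3:**
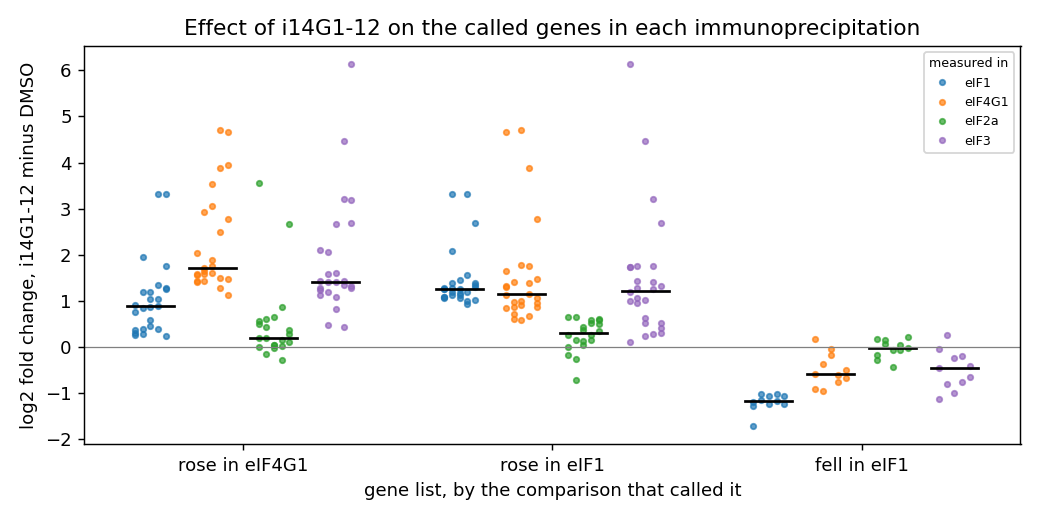
Log2 fold change of i14G1-12 over DMSO (y axis) of the genes called in eIF4G1 or eIF1 (x axis, 3 lists), measured in each immunoprecipitation (colour), with 1 point per gene and a black line at the median. The eIF4G1 risers have medians of 0.89 in eIF1 and 1.41 in eIF3, and points in the immunoprecipitation that called a list are selected to be large.

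The title of the series names eIF1 and eIF4G1 together, so the effects in these were compared directly, in 1 fit to all 20 libraries. Among 9426 genes, 3 differed, each with a smaller effect in eIF1. ENSG00000204388 had a log2 fold change of 0.48 in eIF1 and 3.53 in eIF4G1, a difference of -3.05 (SE 0.52, edgeR adjusted p = 0.00220). Its DMSO level was 1374 ± 130 CPM in eIF1 and 198 ± 28.0 in eIF4G1 (SD, n = 3 each), and after i14G1-12 it was 1920 ± 103 and 2299 ± 800 (SD, n = 3 each). ENSG00000204389 differed by -2.49 (SE 0.52, edgeR adjusted p = 0.0340). Whether ENSG00000204388 and ENSG00000204389 share reads was not checked, so they may not be 2 separate results. For ENSG00000178951 the difference of -5.57 (edgeR adjusted p = 0.0340) came from a single library, eIF4G1 i14G1-12 1, which held 799 counts where no other library had more than 33. It was -0.17 without that library (edgeR adjusted p from 0.000132 to 1.000 over all libraries left out). ENSG00000204389 lost the threshold without any 1 library of eIF1 or eIF4G1 other than eIF1 DMSO a, eIF4G1 i14G1-12 2 and eIF4G1 i14G1-12 3 (edgeR adjusted p up to 0.259), and 1 gene was called without eIF1 DMSO b or c, any i14G1-12 library of eIF1, or eIF4G1 DMSO 1 or 3. Only 295 genes had an unadjusted p under 0.05, where 471 were expected. ENSG00000204388 and ENSG00000204389 were also the 2 genes whose effect differed between the 4 immunoprecipitations (edgeR adjusted p = 0.00321 and 0.00535; 1 gene without eIF4G1 DMSO 1 and 5 without eIF3 i14G1-12 1).

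The DMSO libraries were compared to describe what each immunoprecipitation held without the compound. Factor, antibody, library batch and, for eIF1 and eIF2a, the HA tag and the cells that carry it cannot be told apart. IDs were not matched to names here, so whether any gene printed below encodes a tagged factor was not checked. eIF1 differed from the mean of the others in 354 genes that were higher and 31 that were lower. Scaling to total counts gave 109 higher and 97 lower, and 82 genes were called without eIF1 DMSO a, 240 without eIF1 DMSO c and 211 without eIF2a DMSO 1. ENSG00000175874 was at 131 ± 86.4 CPM in eIF1 (SD, n = 3) and 2.01 ± 3.00 in the others (SD, n = 7; log2 difference 6.54, SE 0.65, edgeR adjusted p = 1.46e-10). ENSG00000156475 was at 41.7 ± 27.7 CPM in eIF1 (SD, n = 3) and had 0 counts in all 7 others, at least 37.0-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 1.03e-05). ENSG00000101150 was lower, at 69.0 ± 7.36 against 291 ± 197 CPM (SD, n = 3 and 7; edgeR adjusted p = 3.43e-05, but 0.0595 without eIF2a DMSO 1). ENSG00000173812, singled out after its values were seen, took 8.90% ± 4.52 of counts in eIF1 DMSO and 10.2% ± 5.66 in eIF1 i14G1-12 (SD, n = 3 each), and means of 0.1003% to 0.326% in the other groups (edgeR adjusted p = 3.74e-19 in DMSO). The contrasts of eIF4G1, eIF2a and eIF3 called 11, 5 and 9 genes. ENSG00000154237 was lower in eIF4G1, at 39.95 ± 35.4 against 262 ± 149.9 CPM (SD, n = 3 and 7; edgeR adjusted p = 6.86e-05). ENSG00000134001 was higher in eIF2a, at 836 ± 464 against 177 ± 62.8 CPM (SD, n = 2 and 8; edgeR adjusted p = 0.00455), and lost the threshold without either eIF2a DMSO library. ENSG00000176463 was higher in eIF3, at 237 ± 0.704 against 37.8 ± 37.4 CPM (SD, n = 2 and 8; edgeR adjusted p = 0.000268, but 0.0916 without eIF2a DMSO 1). For eIF4G1 the number called was 3, 6, 7 and 17 without eIF4G1 DMSO 3, eIF4G1 DMSO 1, eIF2a DMSO 1 and eIF3 DMSO 1. For eIF2a it was 0 and 3 without its DMSO 1 and 2, and 8 without eIF3 DMSO 2 or either eIF3 i14G1-12 library, and for eIF3 it was 1, 5 and 41 without eIF2a DMSO 1, eIF3 DMSO 2 and eIF3 DMSO 1.

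The effect of i14G1-12 was set against sequence length. Spearman's rho across genes was -0.000106 in eIF1, -0.00511 in eIF4G1 and -0.0664 in eIF2a. In eIF3 it was 0.265, with median log2 fold changes of -0.21 for sequences up to 2163 nt and 0.21 for those of 5822 nt or more. Within replicate numbers 1, 2 and 3 the eIF4G1 rho was -0.0513, -0.191 and 0.193. Within numbers 1 and 2 it was -0.0269 and -0.0481 in eIF2a, and 0.133 and 0.116 in eIF3. The eIF3 rho not split by number was -0.161 without eIF3 DMSO 1, -0.113 without eIF3 i14G1-12 2, 0.426 without eIF3 DMSO 2 and 0.470 without eIF3 i14G1-12 1. The risers of eIF4G1 had a median length of 2013 nt, at percentile 33.0 of 10000 random lists matched on expression, and those of eIF1 2104 nt, at percentile 11.2. The eIF1 fallers had a median length of 2831 nt, at percentile 77.3 of such lists.

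**Figure D4:**
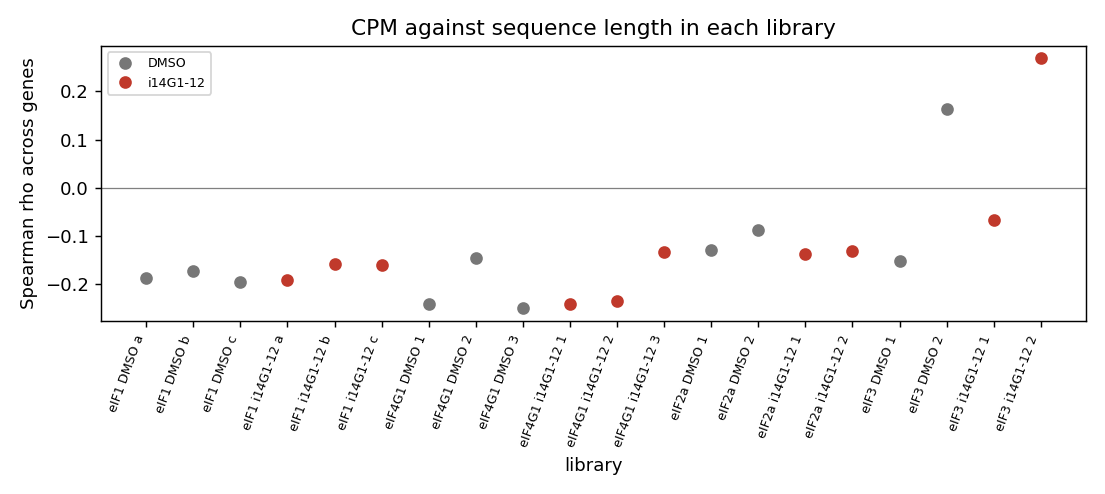
Spearman's rho across genes between CPM and sequence length (y axis) in each library (x axis), 1 point per library, grey for DMSO and red for i14G1-12. The points are above 0 only in eIF3 DMSO 2 (0.163) and eIF3 i14G1-12 2 (0.268).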

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

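The tests of 1 library at a time, those of eIF1 and of eIF2a alone and the look at which libraries a regrouping put together were chosen after the result was seen. The i14G1-12 effect in eIF1 minus that in eIF4G1, tested as an interaction, was -3.05 for ENSG00000204388, -2.49 for ENSG00000204389 and -5.57 for ENSG00000178951 on the log2 scale. Leaving out each of the 20 libraries, the difference nearest 0 was -2.73 for ENSG00000204388 and -2.13 for ENSG00000204389, although the adjusted p of ENSG00000204389 reached 0.259. For ENSG00000178951 it was -0.17, so 1 library may account for that difference. In 32 of 100 regroupings of treatment within eIF1 and within eIF4G1 as many genes were called, and the highest other count was 44. As many were called in 10 of 11 regroupings that mixed only eIF1, which turns a treatment effect in eIF4G1 into a difference, in 1 of 6 that mixed only eIF4G1, and in 20 of 82 that mixed both. Of these 82, 42 kept as many true DMSO libraries in each, where equal treatment effects cancel, and 8 of the 42 gave as many genes, so chance was not excluded for a count of 3 genes.

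The eIF4G1 risers had smaller i14G1-12 effects in both HA immunoprecipitations than in eIF3, a difference not tested for the list as a whole. A lower level after treatment is argued against in eIF1, at a median log2 difference from eIF3 of 0.85 in i14G1-12 (19 of 25 higher; quartiles 0.02 and 1.30), and stays open in eIF2a, at -0.30 (4 of 25 higher), while their mean of 0.28 joins opposite values and decides nothing. A higher level before treatment stays open, with a median of 1.29 in DMSO (22 of 25 higher, and -0.08 for all genes). For each gene in 1 fit, the difference in effects is the difference in treated levels minus that in DMSO. Smaller effects without lower treated levels therefore require a higher DMSO level, so this value restates the pattern and does not test an explanation. The eIF3 DMSO libraries enter both the eIF3 effect and this value, so low values there could give part of it. The tag, the cells that carry it, the antibody and the factor itself were not told apart by any test.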

How the results depend on the processing

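The list tests, the replicate block on sequence length and the fit to 17 libraries were chosen after the data were seen. Of the alternatives to counts, correlations and rho, 242 kept their value within the set bounds and 93 did not. For named genes and lists 608 kept direction and side of the threshold, 83 lost the threshold, 14 passed it and 1 reversed. The causes were not tested, except that fewer libraries or genes are the alternative itself. The eIF1 count of 38 became 129 with no filter, 66 at 30 or more counts, 147 by DESeq2, 4 in a fit of all 20 libraries and 2 to 64 leaving out each library. The eIF4G1 count of 25 became 68, 46 and 75 by the first 3 of these and 4 to 46 leaving out each library. The eIF2a count ranged from 0 to 13. The eIF3 count of 1 became 0 with total counts, 2 with no filter, 2 at 30 or more counts, 3 by DESeq2, 5 in a fit of all libraries, 38 with the replicate number as a block (35 higher and 3 lower) and 0 to 3 leaving out each library. The block gave 31 genes in eIF4G1 and 0 in eIF2a. Deviations from group means of libraries with the same number correlated at 0.520 in eIF3, over only 2 numbers, at -0.000796 in eIF2a and at 0.00597, -0.111 and -0.155 in eIF4G1, so the numbers were not shown to pair libraries. Of 9 lists 8 passed, against 0 with an estimated correlation, 1 by fry and 6 to 9 leaving out each library. The eIF1 risers in eIF2a reversed without eIF2a i14G1-12 1 (adjusted p = 0.403; 0.00208 to 0.910 leaving out each eIF2a library). Effects that differed between eIF1 and eIF4G1 numbered 1 to 3, and between all 4, 1 to 5, with 5 with no filter. In DMSO, total counts gave 206 genes for eIF1 and 8 for eIF2a. No filter gave 19 for eIF4G1, 8 for eIF2a and 17 for eIF3. The 10 DMSO libraries alone gave 20, 13 and 29 for these, DESeq2 gave 7 for eIF4G1 and 15 for eIF3, and 17 libraries gave 3 for eIF3. Leaving out each library gave 82 to 484 for eIF1, 3 to 17 for eIF4G1, 0 to 8 for eIF2a and 1 to 41 for eIF3. Pearson's r then ranged from 0.346 to 0.471 for eIF1 and eIF4G1, -0.00775 to 0.118 for eIF1 and eIF2a, 0.204 to 0.408 for eIF1 and eIF3, -0.0399 to 0.107 for eIF4G1 and eIF2a, 0.174 to 0.432 for eIF4G1 and eIF3 and -0.0399 to 0.0923 for eIF2a and eIF3. The rho with length ranged from -0.0265 to 0.0614 in eIF1, -0.105 to 0.0817 in eIF4G1, -0.0601 to -0.0191 in eIF2a and -0.161 to 0.470 in eIF3. Where this left 1 library in a group, that library is assumed to vary like the others. The 17 preset lists, the shares of RNA classes, the 5′ UTR comparison and the runs without mitochondrial, histone or noncoding RNA genes were not run, as the IDs have no names. In eIF2a DMSO 2 a count of 0 allows up to 299 CPM.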

Other observations

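The test of the eIF3 libraries numbered 2, the rule that set aside the thinning test, and the look at which libraries a regrouping put together were chosen after the result was seen. The i14G1-12 effect in eIF3 rose with sequence length (rho 0.265). With the replicate number as a block rho was 0.162, between the bounds of 0.13 and 0.2 set for that test, which therefore gave no verdict. Within numbers 1 and 2 rho was lower than 0.265, at 0.133 and 0.116. Leaving out each library, rho ran from -0.161 without eIF3 DMSO 1 to 0.470 without eIF3 i14G1-12 1. Its size and sign thus depended on which libraries were compared. With the 4 libraries thinned to 59179 counts rho was 0.0487, but it was already 0.140 before thinning in the 1277 genes left, so unequal depth cannot be told apart from the loss of genes. No biological explanation was tested.

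More genes were higher than lower in eIF1 than in the other immunoprecipitations in DMSO. A larger mean depth of the eIF1 libraries is argued against. With the eIF1 DMSO libraries thinned to 359673 counts, the mean of the others, 93.5% of called genes were higher, against 91.9% before. The other DMSO libraries still ran from 10033 to 1003544 counts, so uneven depth among them was not tested and stays open. The role of 1 gene taking much of the counts cannot be told apart, because the bounds set for that test could be met in both directions and were. Without ENSG00000173812 the share moved by -0.171 percentage points under TMM, which trims such a gene, while under total counts it was 73.5% without that gene and 52.9% with it. Whether ENSG00000173812 encodes the tagged factor was not checked, as IDs were not matched to names. The factor, the antibody, the library batch, the HA tag and the cells that carry it stay open and untested.

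The real grouping of the eIF1 libraries gave 38 changed genes and the highest of the other splits 0, and for eIF4G1 these were 25 and 4. In each, 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. For the eIF1 contrast in DMSO, 1 of 100 regroupings, the real one, gave as many as 385 genes and the highest other 131. A random grouping of these libraries is argued against. As replicates may be technical, a chance difference between cultures or preparations was not excluded. For eIF4G1 in DMSO, 14 of 100 gave as many as 11 genes and the highest other 433, which points to a structure of the samples. That regrouping put the 3 eIF1 libraries together, and among all 13 with as many genes, the real one aside, 10 put 2 of them together and 2 put all 3 together, so the share does not decide whether chance gives 11 genes. As many genes were called in 1 of 33 regroupings with 0 eIF1 libraries in the place of eIF4G1 and in 0 of 47 with 1.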
